A study of Drosophila melanogaster with 2 samples.

How the data were processed

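Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, aged 0 to 24 hours, from a transgenic line that carries CG17829 fused at its C terminus to green fluorescent protein (GFP), per the labels. The protein was pulled down with an antibody against GFP. The labels give 1 group with 2 biological replicates, numbered 2 and 4, which are separate biosamples of 1 line. They also give a size range of 200 to 800 without a unit. There was no second condition, so no comparison between treatments, ages or genotypes could be made.

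The authors deposited 4 peak lists in the dm6 genome build, per the deposited provenance notes: 1 list for each replicate, 1 list from both replicates together, called here the pooled list, and 1 list thresholded by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks repeat between replicates. Each replicate list and the pooled list was made from read alignments and 1 control alignment, and the IDR list was derived from the other lists, per the deposited notes. The aligner and the peak caller are not given in the sources used here. The signal value of each peak is the authors' own deposited value on a scale that the sources do not define, so it was used only to rank and describe peaks within a list. The deposited −log10 q values were inspected and took no part in a test. Peak starts, ends and summit offsets are deposited positions with no normalization, the other unit in these lists. Each replicate list and the pooled list held 30000 peaks, and the IDR list held 7915 peaks, which were exactly the 7915 strongest of the pooled list. A list of fixed length was ranked and ended by the authors' processing, not by the biology. Signal tracks and reads were not analysed here, and the read depth of the samples is unknown.

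The dm6 coordinates were read with the gene annotation of Ensembl 115 for BDGP6.54, which has the coordinates of dm6, and with the NCBI RefSeq sequence of the same assembly. No peak ended past its chromosome arm. Only the arms 2L, 2R, 3L, 3R, 4 and X were used, and all peaks lay on them. Annotated transposons were left out of the genes, leaving 18164 genes with 23581 distinct transcription start sites (TSSs), of which 13945 genes were protein-coding. Positions are printed counting from 1. CG17829 is named Hinfp in both annotations.

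The tests, the gene lists, the k-mers and most alternatives were chosen before the data were examined. A summit within 250 bp of a TSS counted as a promoter summit. Shares of summits were set against 1000 random placements of the summits on the same arm, which gives a smallest possible two-sided p of 0.002 and a smallest possible one-sided p of 0.001. Replicate overlap was tested one-sided in the 7915 strongest peaks of each replicate, with an overlap of 1 bp or more. Annotation classes were tested in the order promoter, 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Peaks per arm were set against the arm's share of TSSs with a chi-square test and an exact binomial test per arm. For each of 26 gene lists, genes with an IDR summit within 250 bp of a TSS were set against all other protein-coding genes with Fisher's exact test, two-sided. For 7 symbols of these lists no single protein-coding gene was matched, and those symbols were left out. A further 6 symbols were second names of a member and added no gene. For each of 15 k-mers, windows of 50 bp to each side of the summit were set against windows centred 500 bp away on each side, with Fisher's exact test. The rank of each k-mer among all k-mers of the same base composition was also taken. All 32896 8-mers, each counted with its reverse complement, were searched on arms 2L, 2R and 4 and tested again on arms 3L, 3R and X, each time one-sided for excess at summits with Fisher's exact test, and their ratios were formed after adding 1 to each count. The promoter share of the strongest 20% of IDR peaks was compared with that of the weakest 20% by a two-sided permutation test with 100000 resamples, whose smallest possible p is 1e-05. Adjusted p-values follow Benjamini and Hochberg within each family at a threshold of 0.05.

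The genes named were fixed by a rule. They are the gene with the nearest TSS, within 250 bp, of each of the 20 strongest IDR peaks that also overlap a peak of both replicate lists, the 4 members with the strongest promoter summit in each gene list that passed and the 1 strongest in each list that did not, CG17829 itself, and the replication-dependent histone genes as a group. The promoter of rank 19 is the exception, and it is not described here. Many of the promoters are shared with a second gene, which is named in only some cases. Anything named outside this rule is said to be so.

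Intervals are exact Clopper-Pearson intervals at 95%, and the limit for a count of 0 is 3 counts of the total. Intervals and limits cover counting error only. The p-values measure spread over peaks, genes or random places, not between animals, and neighbouring peaks and genes with a shared promoter are not independent. The alternatives changed the overlap rule, the distance to a TSS, the order of classes, the random placement, the background genes, the window size and the flanks. They also took the strongest 50% of the IDR peaks, or left out 1 replicate by using the 7915 strongest peaks of the other. The programs were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The statistics were tested on simulated data. Of 20 sets of random peaks, 0 were called different in promoter share. Of 80 simulated lists with an odds ratio of 4, 77 were called, and of 380 lists with no shift, 2 were called. An 8-mer planted in 200 windows was found and held, with 0 unrelated 8-mers held. Both sets of windows in that simulation were flanks. It therefore did not test how many 8-mers hold through a difference in base composition between summits and flanks.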

Results

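Binding of CG17829, the Drosophila homologue of histone H4 transcription factor (gene symbol Hinfp), was measured by ChIP-seq in embryos aged 0 to 24 hours that carried the protein fused to GFP. The group held 2 biological replicates, numbered 4 and 2. The strongest peak signal was 3039 in the list of replicate 2 and 2546 in that of replicate 4, in the authors' signal values, which are not on a stated scale. The median peak width was 416 bp in replicate 2, 424 bp in replicate 4 and 430 bp in the IDR list. The read depth is unknown, so the precision of a single peak's signal could not be given. No position with its summit and signal was shared between the replicate lists, so the lists were not copies of one another.

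The first comparison asked how far the peaks of the replicates coincided. The strongest places were the same in both: all 20 of the strongest IDR peaks ranked within the first 20 peaks of replicate 2 and the first 23 of replicate 4. Of the 7915 strongest peaks of replicate 2, 83.8% (95% interval 82.96 to 84.6) overlapped one of the 7915 strongest of replicate 4, and 84.7% did in the other direction. Random placement gave 4.02% ± 0.222 (SD of 1000 placements), and the one-sided p of 0.001 was the smallest they could give. In the IDR list, 7828 peaks (98.9%) overlapped a peak in both replicate lists, a list that was itself selected for agreement between the replicates. Over these peaks the log10 signal values had Spearman's rho 0.790 and Pearson's r 0.852, a correlation across peaks, which are not independent replicates. The median distance between the paired summits was 24 bp.

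**Figure D1:**
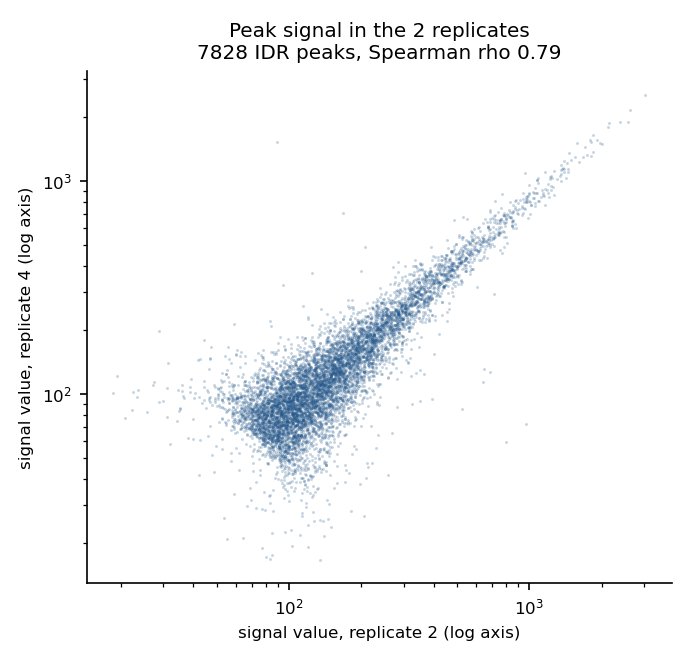
Signal value of each of 7828 IDR peaks in replicate 2 (horizontal) and replicate 4 (vertical), both on log axes in the authors' units, 1 point per peak. Spearman's rho was 0.790 over these points.

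Summits lay at gene starts more often than random places, and hardly at all in coding sequence. Of the 7915 IDR summits, 3809 (48.1%, interval 47.0 to 49.2) lay within 250 bp of a TSS, against 7.52% ± 0.283 (SD) at random places, a ratio of 6.402. Only 17 summits (0.215%) lay in coding exons outside promoters, against 15.5% at random places. Introns held 31.3% against 41.1%, intergenic sequence 17.4% against 28.6%, 3' UTRs 0.948% against 4.75% and 5' UTRs outside promoters 0.796% against 1.32%. The median distance of a summit to the nearest TSS was 290 bp.

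The two-sided p for the promoter share was 0.002, the smallest that the placements could give. The other classes named had an adjusted placement p of 0.00233, and only other exons, at 1.17% against 1.19%, did not pass (adjusted placement p of 0.919). The class of the first exon depended on the order of classes. With exons and introns counted before promoters, 5' UTRs held 10.95% of summits against 3.37% at random places, promoters outside transcripts 29.1% against 2.02%, and other exons 2.44% against 1.77% (adjusted placement p of 0.002 each).

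**Figure D2:**
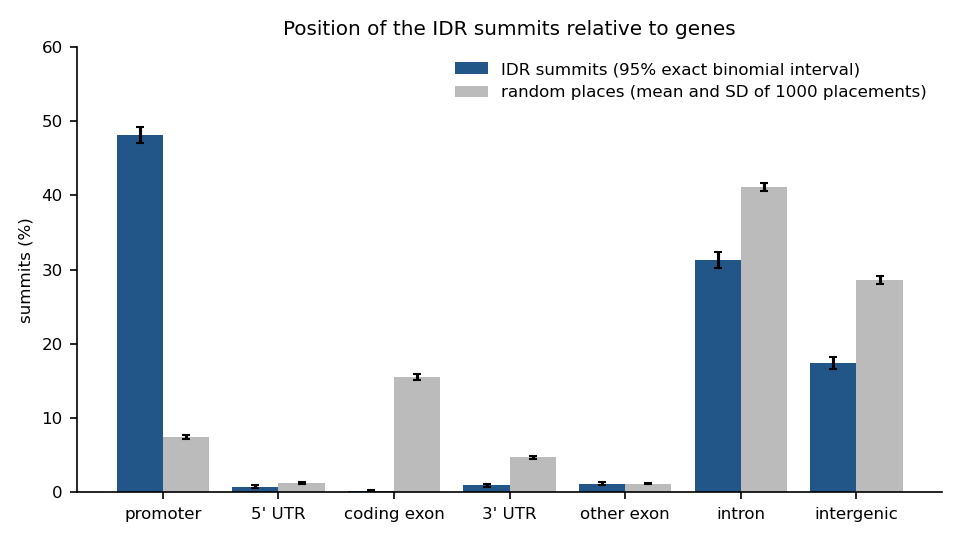
Percent of 7915 IDR summits in each class of sequence (blue bars, 95% exact binomial interval) beside the mean of 1000 random placements on the same arm (grey bars, SD). Promoters held 48.1% of summits against 7.52%, and coding exons 0.215% against 15.5%.

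The strongest peaks lay at both promoters and introns of genes of many kinds. Of the 20 strongest, 12 had a TSS within 250 bp. Among these were px, a wing vein gene (chromosome 2R, peak 22514027 to 22514555, dm6, rank 2, signal 4758), Ugalt, a UDP-galactose transporter (X, 2703638 to 2704122, rank 5, signal 3997), and the shared promoter of Art3, an arginine methyltransferase, and mRpS10, a mitochondrial ribosomal protein (3R, 15229300 to 15229775, rank 6, signal 3905). The segmentation gene odd had rank 7 (2L, 3606411 to 3607032, signal 3482, summit 25 bp from the TSS). Chro, which encodes the chromatin protein Chromator, shared the peak of rank 16 with Ssl1, a subunit of the transcription factor TFIIH (3L, 22878685 to 22879156, signal 3092). The promoter shared by CG18428 and eIF4EHP, a cap-binding repressor of translation, had rank 18 (3R, 24108900 to 24109436). The promoter of rank 19 is not described here.

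The other promoters among the 20 were those of CG18549 (rank 8), CG1888 (rank 11), Fkbp14, a peptidyl-prolyl isomerase (rank 12), CG11309 with CG7632 (rank 13) and CG14100 (rank 17). The remaining 8 peaks had no TSS within 250 bp, and their host genes were named after the values were seen. The strongest peak of all lay in the 3' UTR of para, the voltage-gated sodium channel gene, 7662 bp from the nearest TSS (X, 16456372 to 16457148, signal 5569, rank 1 in both replicates). Introns of CG11050 (rank 3), ush, which encodes a cofactor of GATA factors (rank 4), the Polycomb group gene ph-p (rank 10), tna (rank 14), the kinase gene Lk6 (rank 15) and CG32772 (rank 20) held 6 more, and 1 was intergenic on 3R (rank 9, 16221499 to 16223129).

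Genes of ribosomal proteins, of the proteasome and of oxidative phosphorylation had a promoter summit more often than other genes. Of 13945 protein-coding genes, 4416 (31.7%) had an IDR summit within 250 bp of a TSS. Among genes of cytosolic ribosomal proteins the count was 74 of 85 (87.1%, odds ratio 14.7, adjusted exact p = 3.47e-25), with RpL34b (rank 272, promoter shared with CG8132), RpS27 (rank 454, shared with Nup37), RpL36 (rank 491) and RpL32 (rank 527, shared with CG7943) the strongest. Genes of mitochondrial ribosomal proteins followed with 49 of 73 (67.1%, odds ratio 4.44, adjusted exact p = 2.71e-09), among them mRpS10 (rank 6), mRpL41 (rank 38), mRpL23 (rank 77) and mRpL24 (rank 150). The proteasome list had 26 of 32 (81.2%, odds ratio 9.40, adjusted exact p = 4.43e-08), led by Rpn3 (rank 937), Prosbeta2 (rank 1589, shared with mRpL39), Rpn6 (rank 1645) and Rpn11 (rank 2178). Oxidative phosphorylation had 41 of 78 (52.6%, odds ratio 2.40, adjusted exact p = 0.000305), with ND-MWFE (rank 687), ND-51 (rank 931), ND-23 (rank 1151) and ND-SGDH (rank 1406), all subunits of complex I. In the strongest 50% of the IDR peaks oxidative phosphorylation did not pass (odds ratio 1.79, adjusted exact p = 0.0665). The promoters of mRpL24 and ND-MWFE are each shared with a gene not named here, whose TSS was nearer to the summit.

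Genes of splicing, general transcription, Polycomb and Trithorax, the cell cycle and DNA replication were also bound above the rate of other genes. Splicing factors had 24 of 30 (80.0%, odds ratio 8.67, adjusted exact p = 1.96e-07), with U2af50 (rank 384), snRNP-U1-C (rank 643), SF2 (rank 1114) and Sf3b1 (rank 1562). General transcription machinery had 27 of 35 (77.1%, odds ratio 7.32, adjusted exact p = 1.51e-07), with Taf5 (rank 292), Polr2B (rank 321), which encodes a subunit of RNA polymerase II, TfIIA-L (rank 715) and MED31 (rank 810). Polycomb and Trithorax group genes had 21 of 28 (75.0%, odds ratio 6.50, adjusted exact p = 7.95e-06), among them brm, the ATPase of the Brahma remodelling complex (rank 90), E(z), the histone H3 lysine methyltransferase of Polycomb repression (rank 148), Sfmbt (rank 1520) and Jarid2 (rank 2177). Cell cycle genes had 31 of 43 (72.1%, odds ratio 5.61, adjusted exact p = 1.96e-07), with tum (rank 414), the centriole kinase gene SAK (rank 828), Dp, a partner of E2F (rank 1190), and aurA (rank 1829). The matching peak at aurA ranked 1585 in replicate 2 and 5468 in replicate 4. DNA replication genes had 24 of 42 (57.1%, odds ratio 2.89, adjusted exact p = 0.00142), with the DNA polymerase subunit gene PolD2 (rank 194), RnrS of ribonucleotide reductase (rank 403), Mcm2 (rank 1508) and Top2 (rank 2005). In the strongest 50% of the IDR peaks DNA replication did not pass (odds ratio 1.72, adjusted exact p = 0.225). The promoters of U2af50, Taf5, MED31, brm and Jarid2 are each shared with a gene not named here, whose TSS was nearer to the summit.

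Genes that make or serve histones outside the cluster were mostly bound. The histone locus body and histone mRNA processing list had 10 of 12 (83.3%, odds ratio 10.8, adjusted exact p = 0.000732), with CstF64 (rank 1107, shared with a gene whose TSS was nearer), Slbp, the histone stem-loop binding protein (rank 2810), mxc, a scaffold of the histone locus body (rank 3165, shared with Larp7), and Cpsf100 (rank 4504). Of the 6 replication-independent histone genes, 5 were bound (odds ratio 10.8, adjusted exact p = 0.0215): the strongest were His2Av (rank 1487, shared with ball), His4r (rank 2560, shared with put), His3.3B (rank 2626) and His3.3A (rank 3445). Without replicate 2 neither list passed, with odds ratios of 3.21 (adjusted exact p = 0.0826) and 4.59 (adjusted p = 0.0953). In the strongest 50% of the IDR peaks the first list did not pass (odds ratio 1.61), and the second did not within 100 bp of a TSS (2.25), within 1000 bp (7.49) or against lists matched on the number of TSSs.

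Homeotic, segmentation and dorsoventral patterning genes of the early embryo were bound above the rate of other genes as well. Homeotic and segmentation genes had 19 of 34 (55.9%, odds ratio 2.74, adjusted exact p = 0.00779), led by odd (rank 7), gsb (rank 319), hry, the gene hairy (rank 1062), and bcd, the anterior determinant (rank 1558). Dorsoventral patterning genes had 16 of 27 (59.3%, odds ratio 3.15, adjusted exact p = 0.00606), with the heart gene tin (rank 242), cact, the inhibitor of Dorsal (rank 395), and the T-box genes Doc1 (rank 1942) and Doc3 (rank 2488). The matching peak at Doc1 ranked 1819 in replicate 2 and 7354 in replicate 4. In the strongest 50% of the IDR peaks neither list passed (adjusted exact p = 0.444 and 0.505), and without replicate 2 the dorsoventral list did not (odds ratio 2.13, adjusted p = 0.0832). Within 100 bp of a TSS the homeotic and segmentation list did not pass (odds ratio 1.62).

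Cuticle, chemoreceptor, chorion and muscle genes were bound below the rate of other genes. No cuticle protein gene had a promoter summit (0 of 118, which allows up to 2.54%, adjusted exact p = 2.60e-19), and no odorant or gustatory receptor gene did (0 of 179, up to 1.68%, adjusted p = 4.76e-29). Chorion and vitelline membrane genes had 0 of 16 (up to 18.75%, adjusted exact p = 0.00779), and muscle structural genes 2 of 23, Tm1 (rank 3496) and Zasp52 (rank 4308), with an odds ratio of 0.205 (adjusted p = 0.0320). The matching peak at Tm1 ranked 4190 in replicate 2 and 8069 in replicate 4. Without replicate 4 the muscle list did not pass (odds ratio 0.317, adjusted exact p = 0.0836), nor did it with a TSS distance of 100 bp (odds ratio 0.428, adjusted p = 0.488) or 1000 bp (0.654, adjusted p = 0.452). In the strongest 50% of the IDR peaks the muscle list did not pass either (1 of 23, odds ratio 0.219, adjusted exact p = 0.232). Chorion genes, still with 0 bound, did not pass within 100 bp or in the strongest 50% of the IDR peaks.

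For 8 lists the test was not passed. The signalling pathway list had 16 of 33 (adjusted exact p = 0.0803), with spi, an EGF receptor ligand gene, at rank 224. The heat shock list had 8 of 18 with Hsp27 at rank 141, the DNA repair list 14 of 32 with Irbp, the Ku70 gene, at rank 219, and the insulator list 8 of 16 with Chro at rank 16. Transposon silencing had 12 of 30 with spn-E at rank 1151, the peak it shares with ND-23, germ cell genes 5 of 19 with bgcn at rank 1741, blood cell genes 4 of 17 with gcm at rank 770, and neuronal synaptic genes 4 of 24 with elav at rank 69. Adjusted p ran from 0.167 to 0.806 in these 7. Signalling (odds ratio 3.72), DNA repair (2.41) and insulators (3.54) passed without replicate 4. Signalling also passed within 100 bp and 1000 bp of a TSS, DNA repair and neuronal genes within 1000 bp, and insulators in the strongest 50% of the IDR peaks.

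Some lists passed in these settings with an odds ratio that moved over 1.5 times. Without replicate 4 it was 4.68 for the proteasome, and without replicate 2 it was 5.37 for splicing. In the strongest 50% of the IDR peaks it was 7.38 for cytosolic ribosomal proteins, 2.54 for the proteasome, 3.23 for splicing, 2.86 for general transcription machinery, 3.64 for Polycomb and Trithorax and 3.50 for the cell cycle. Within 100 bp of a TSS it was 1.95 for mitochondrial ribosomal proteins, 5.12 for the proteasome, 3.45 for splicing, 3.80 for general transcription machinery, 3.91 for Polycomb and Trithorax, 2.95 for the cell cycle and 6.31 for the histone locus body. Of the lists with no bound gene, 1 of 118 cuticle genes was bound without replicate 4, and 5 of 118 cuticle and 3 of 179 receptor genes within 1000 bp of a TSS.

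In total 13 lists passed as higher and 5 as lower than other protein-coding genes. The lower lists include the histone cluster, where sequence is repeated and peaks are hard to place, so its call cannot be read as absence of binding. Against the 6821 genes with a pooled peak within 250 bp of a TSS, 5 lists passed. These were cytosolic ribosomal proteins (74 of 82, odds ratio 5.11, adjusted exact p = 3.81e-06), proteasome (26 of 29, 4.74, adjusted p = 0.0283), general transcription machinery (27 of 30, 4.93, adjusted p = 0.0283) and, on 5 genes each, the histone cluster and the receptors with 0 bound. That background is itself set by binding, since the IDR peaks are the strongest pooled peaks, and it left 2 cuticle genes and 1 chorion gene. Among the lists that lost the call, the odds ratio was 5.46 for the histone locus body and 2.62 for splicing, but near 1 for homeotic and segmentation genes (1.03) and DNA replication (0.933), and 1.40 for oxidative phosphorylation and 1.41 for the cell cycle.

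**Figure D3:**
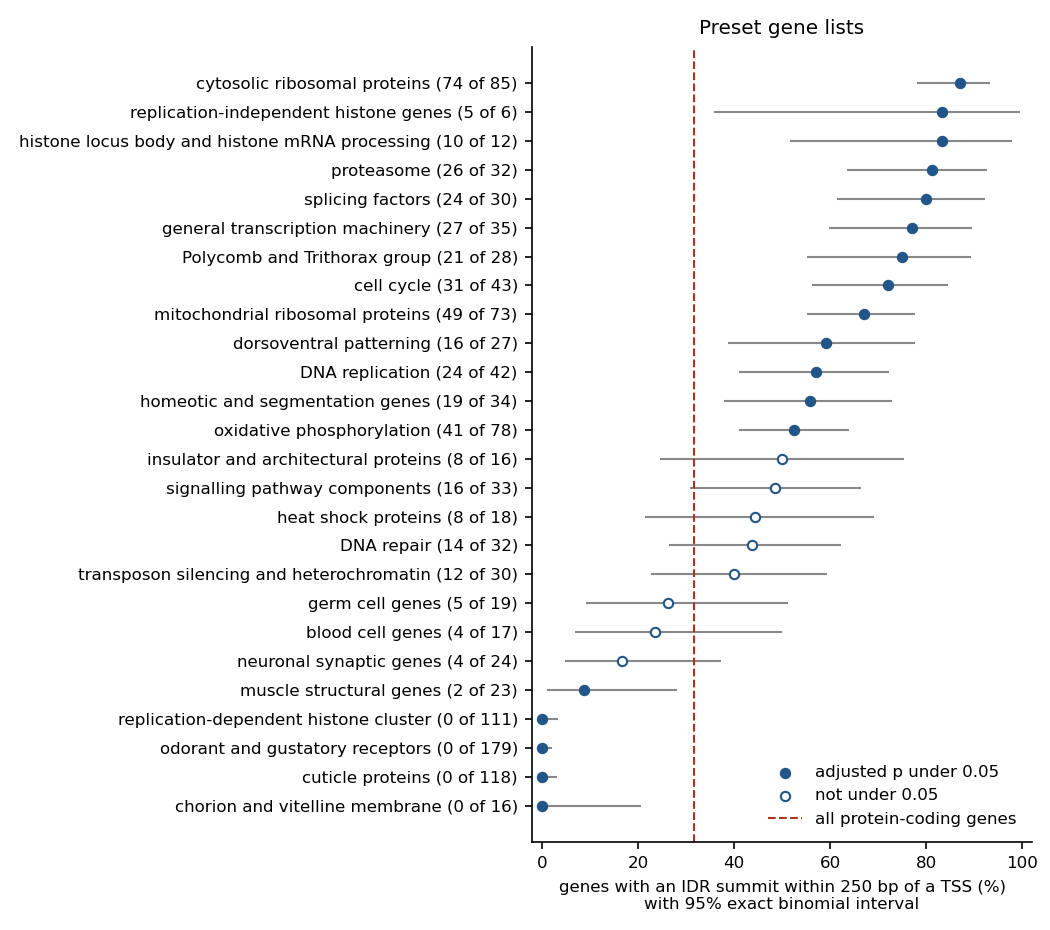
Percent of genes in each of 26 preset lists with an IDR summit within 250 bp of a TSS, with 95% exact binomial intervals, filled where the adjusted p was under 0.05. The dashed line is the 31.7% of all protein-coding genes, and 74 of 85 cytosolic ribosomal protein genes stand highest.

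At its own gene, CG17829 had a promoter peak somewhat below the median signal of the IDR list and a strong neighbour. Hinfp (FBgn0025635) lies on X from 625542 to 628016. The IDR list, with a median signal of 241.3, had 1 summit at the Hinfp TSS and 0 summits in the gene body. The summit at the TSS was at 625477, 65 bp away, with rank 4440 and signal 221.2. An IDR peak that overlaps it had its summit at 625278 (rank 3635), over 250 bp from the Hinfp TSS. Within 5 kb the list had 6 summits, the strongest at the promoter of the ribosomal protein gene RpL36 (summit 629494, rank 491, signal 827.2). Replicate 4 had 1 summit at the Hinfp TSS, with rank 3183, and replicate 2 had 2, with ranks 3375 and 7878, the second of them under the IDR peak at the TSS. The replicate 4 peak of rank 3183 was the match of both overlapping IDR peaks.

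The replication-dependent histone cluster, which holds the genes of the core histones and of histone H1, had no IDR peak. It spans 124.7 kb on 2L (21416953 to 21541681) with 111 annotated genes, and 0 of 111 were bound, which allows up to 2.70% (adjusted exact p = 4.78e-18). The pooled list had 4 peaks inside it, the best at rank 13067, replicate 2 had 4 and replicate 4 had 3. The best of replicate 4, at 21425124 and rank 7694, was within its 7915 strongest. Sequence in the cluster is repeated: 0.978% of its 32-mers occurred once in the genome sequence, so peaks there are hard to place. The count of 0, its limit and its p therefore cannot be read as absence of binding. Without replicate 2, 2 of 111 genes were bound (1.80%, interval 0.219 to 6.36).

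The number of peaks on the chromosome arms did not follow the number of TSSs exactly. Arm 3L had 1752 peaks, 1.15 times the number given by its share of TSSs (adjusted exact p = 1.21e-09), and 2R had 1458, 0.892 times (adjusted p = 2.29e-06). Chromosome 4, the small and largely heterochromatic chromosome, had 34 peaks, 0.554 times (adjusted exact p = 0.000384). Arms 2L (0.958), 3R (0.999) and X (1.03) did not pass, with adjusted p of 0.101, 0.958 and 0.226. X passed without replicate 4 (1.06 times, adjusted exact p = 0.0338), and 2L without replicate 2 (0.949 times, adjusted p = 0.0389). The chi-square over the 6 arms was 69.3 with 5 degrees of freedom (p = 1.46e-13). Without replicate 4, chromosome 4 had 56 peaks and no longer passed (0.912 times, adjusted exact p = 0.677), and with numbers expected from arm length 2R did not (0.974 times, adjusted p = 0.301) and 2L was above the expected number (1.06 times, adjusted p = 0.0242).

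Few summits were placed in annotated transposons. Only 19 IDR summits (0.240%) lay in an annotated transposon insertion, against 5.83% ± 0.264 (SD) at random places (placement p of 0.002, the smallest possible), a test chosen after the data were seen. Copies of a transposon are repeated sequence, where peaks may be hard to place, and the random places were not restricted to unique sequence. The low share therefore cannot be read as absence of binding. The share of summits on any base masked in the reference was 21.8% against 20.1% ± 0.447 (SD), a ratio of 1.09 (placement p of 0.002). Where 50% or more of the 100 bp around the summit had to be masked, the shares were 12.38% and 12.31% (placement p of 0.845).

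Promoter sequence elements of housekeeping genes were the most concentrated at summits. The DRE, TATCGATA, the element bound by Dref and BEAF-32, was present within 50 bp of 270 of 7915 summits (3.41%) and in 43 of 15830 flanking windows (0.272%), a ratio of 12.6 (adjusted exact p = 3.85e-84). Core promoter motif 1, GGTCACAC, the element bound by M1BP, was present at 227 summits and in 32 flanks, a ratio of 14.2 (adjusted exact p = 8.03e-74). Each ranked first among k-mers of its composition, of 592 and of 1680. At promoter summits against promoters without a pooled peak the ratios were 6.82 for the DRE and 5.38 for motif 1. Distance to the TSS as a part of that comparison was not tested. With flanks 1000 bp away the ratios were 13.8 and 9.46. In windows centred 100 bp to each side of the summit they were still 9.2 and 9.1. Core promoter motif 6, GGTATTTT, had a ratio of 3.59 (adjusted exact p = 9.84e-24), and the CTCF-like AGGTGGCG 2.52 (adjusted p = 6.46e-06), each ranked 2 in its composition. In windows centred 100 bp to each side of the summit the CTCF-like k-mer did not pass (odds ratio 1.09, adjusted exact p = 0.819). The TATA box hexamer had a ratio of 2.18, near the 2.15 that was the median of hexamers of its composition (rank 7 of 15).

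The k-mers taken from the site of the human homologue were not concentrated at summits. The 8-mer ACGTCCGC was present at 8 summits and in 27 flanks (ratio 0.593, adjusted exact p = 0.266), with a median of 0.5 for 8-mers of its composition (rank 271 of 840). The short core CGTCCG was present at 84 summits and in 390 flanks, a ratio of 0.431 (adjusted exact p = 5.88e-14), with a median of 0.485 for hexamers of its composition (rank 37 of 60). Also lower at summits were the hexamer of Pho (0.664), the Zelda heptamer (0.556), the E-box (0.7), the E2F-like 8-mer (0.516) and the GAGA heptamer (0.779), with adjusted p from 1.38e-12 to 0.0216. Beside k-mers of the same composition the GAGA heptamer (rank 4 of 35, median ratio 0.497) and the E-box (rank 34, median 0.640) were above the median ratio, and Pho (rank 141 of 180, median 0.814), Zelda (rank 280 of 420, median 0.685) and the E2F-like k-mer (rank 295 of 560, median 0.550) below it. Against promoters without a pooled peak the GAGA heptamer was instead higher at promoter summits (odds ratio 1.78, adjusted exact p = 0.000159), and the E2F-like, Zelda and E-box k-mers did not pass (adjusted p = 0.865, 0.566 and 0.566). The TATA box also did not pass there (odds ratio 1.08, adjusted exact p = 0.196). The initiator-like k-mer had an odds ratio of 0.334 there (adjusted exact p = 4.88e-69). This k-mer was present in 16.95% of windows at those promoters, 6.38% at promoter summits and 6.61% at all summits. The low odds ratio therefore reflects a high share at those promoters and cannot be read as depletion at summits. Distance to the TSS as a part of this comparison was not tested for any k-mer. The E2F-like k-mer passed in none of the 7 other settings, and GAGA did not pass without replicate 4, with flanks 1000 bp away or with windows of 100 bp to each side. The HINFP-like 8-mer was lower at summits with those windows (odds ratio 0.470, adjusted exact p = 0.0235), where its rank by composition was not taken. The initiator-like, NRF-like and Ets-like k-mers, with ratios of 1.03, 0.714 and 1.00, did not pass against the flanks (adjusted exact p = 0.577, 0.375 and 1).

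The search over all 8-mers found the same elements in sequence rich in A and T. Of 32896 8-mers, 943 were found on 2L, 2R and 4, and 852 of them held on 3L, 3R and X, 739 with at most 2 G or C bases. The highest ratio on the test arms was that of the DRE variant ATCGATAG (11.8, adjusted exact p = 3.98e-47), followed by TATCGATA (10.97) and GGTCACAC (10.75). Among those held, 10 contained ATCGAT and 5 GTCACA. AGCCCTGG (8.44) and CAGCCCTG (7.69), named after their values were seen, had 6 G or C bases. The mean GC content within 50 bp of an IDR summit was 34.7% ± 10.7 (SD), against 42.3% ± 10.1 at random places. With windows of 100 bp to each side, 1611 8-mers held.

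**Figure D4:**
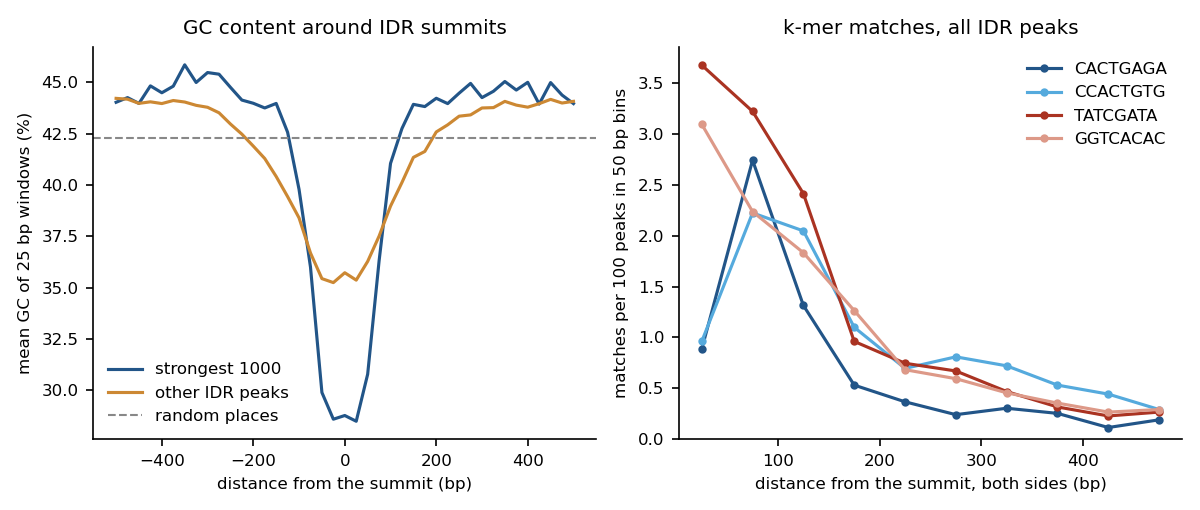
Left: mean GC content in windows of 25 bp by distance from the summit, for the strongest 1000 IDR peaks, the other IDR peaks and random places (dashed, 42.3%). Right: matches of 4 8-mers per 100 IDR peaks by distance from the summit, both sides together, in bins of 50 bp; TATCGATA and GGTCACAC were most frequent within 50 bp, and CACTGAGA and CCACTGTG, chosen after their values were seen, from 50 to 100 bp.

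The relation of peak strength to promoters depended on the distance to the TSS and on the share of peaks compared. The promoter share was 44.5% (interval 42.0 to 46.96) in the strongest 20% of IDR peaks and 45.99% (43.5 to 48.5) in the weakest 20%, a difference of -1.52 percentage points (permutation p = 0.410). The share was not flat between these ends, at 47.4%, 52.7% and 49.97% in the steps of 20% from stronger to weaker, which were not tested. Within 100 bp of a TSS the shares were 15.9% and 33.4%, a difference of -17.5 points (permutation p = 1e-05, the smallest possible). Comparing the strongest with the weakest 50% gave -2.35 points at 250 bp (permutation p = 0.0381). For the strongest and weakest 20% at 1000 bp the difference was 2.15 points in the other direction (permutation p = 0.222). Without replicate 2 the difference between the strongest and weakest 20% at 250 bp was 0.253 points (permutation p = 0.915).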

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

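The test of the peaks outside the IDR list was chosen only after the IDR result was seen. The 22085 pooled peaks that the IDR threshold left out, which no comparison above uses on their own, still lay at promoters more often than random places. Of these, 4544 (20.6%, interval 20.04 to 21.1) had a TSS within 250 bp, against 7.48% ± 0.175 (SD of 1000 placements), a ratio of 2.75 (placement p of 0.002, the smallest possible). The IDR peaks had 48.1%, without a test between the sets. No explanation was tested.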

How the results depend on the processing

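The test of transposon insertions, the placement in bins of 10 kb that hold a pooled peak, the correlation of summits within 100 bp, the windows 100 bp beside the summits, the spacing of summits, and the strength and own-gene results without a replicate were chosen only after the results were seen. Each other setting was planned. Replicate overlap and signal correlation could not be computed with a replicate left out, since each needs both. The promoter share kept its direction and call in all 9 settings, and the replicate overlap in all 4. The signal correlation had a rho of 0.757 over the pooled list and 0.806 for summits within 100 bp.

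With exons before promoters, 5' UTRs held 10.95% of summits and other exons 2.44%, both above random places. Other exons held 1.34% in the strongest 50% of IDR peaks, and 1.19% to 1.31% with a replicate left out, neither passing. The repeat share was 12.4% where 50% of 100 bp had to be masked, and 0.240% for transposon insertions, below random places. By arm length the peak numbers were 1.06 times those given for 2L, 0.974 for 2R and 0.975 for X. In the strongest 50% they were 1.051 for 3R and 0.978 for X. With a replicate left out, the lowest and highest were 0.949 and 0.964 for 2L, 0.998 and 1.02 for 3R, 0.456 and 0.912 for chromosome 4, and 1.03 and 1.06 for X.

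Gene lists are given as odds ratios. Within 100 bp of a TSS they were 2.25 for replication-independent histone genes, 1.62 for homeotic and segmentation genes, 2.58 for signalling, 0.428 for muscle, 1.38 for blood cells and 0 for chorion. Signalling passed there (adjusted exact p = 0.0253) and chorion did not. Within 1000 bp they were 7.49 for replication-independent histone genes, 2.19 for DNA repair, 3.45 for signalling, 0.299 for neuronal, 0.654 for muscle and 1.09 for germ cells. DNA repair (adjusted exact p = 0.0411), signalling and neuronal (0.0300) passed there, and the histone genes (0.0535) did not.

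In the strongest 50% of IDR peaks the ratios were 1.61 for the histone locus body, 1.72 for DNA replication, 1.79 for oxidative phosphorylation, 3.76 for insulators, 1.49 for homeotic and segmentation, 1.38 for dorsoventral, 0.219 for muscle, 1.73 for germ cells and 0 for chorion. Of these, only the insulator list passed (adjusted exact p = 0.0278). With lists matched on the number of TSSs, the ratio of observed to matched genes was 2.28 for replication-independent histone genes, which did not pass (adjusted permutation p = 0.0646), and 0.399 for neuronal genes, which did (0.0217).

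Against genes with a pooled peak 5 lists passed. The odds ratios of those that did not, or that turned, were 2.73 for replication-independent histone genes, 5.46 for the histone locus body, 0.816 for transposon silencing, 0.933 for DNA replication, 1.41 for cell cycle, 0.953 for DNA repair, 1.68 for mitochondrial ribosomal proteins and 1.40 for oxidative phosphorylation. They were 2.62 for splicing, 2.29 for Polycomb and Trithorax, 0.871 for insulators, 1.03 for homeotic and segmentation, 1.75 for dorsoventral, 0.579 for signalling, 1.09 for neuronal, 0.181 for muscle, 1.36 for germ cells, 1.09 for blood cells, 0 for cuticle and 0 for chorion.

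With a replicate left out, the lowest and highest odds ratios were 4.59 and 10.6 for replication-independent histone genes, 3.21 and 10.6 for the histone locus body, 1.57 and 2.41 for DNA repair, 2.30 and 3.54 for insulators, 2.13 and 3.09 for dorsoventral, 2.16 and 3.72 for signalling, 0.218 and 0.317 for muscle, and 1.24 and 1.34 for germ cells. The own gene had 5 and 6 summits within 5 kb.

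Odds ratios of k-mers with flanks 1000 bp away were 0.990 for GAGA, 0.804 for Zelda and 0.666 for E2F-like, none passing. With windows of 100 bp to each side they were 0.953 for GAGA, 0.866 for E2F-like and 0.470 for the HINFP-like core, which passed (adjusted exact p = 0.0235), and 1611 8-mers held. Promoter peaks against promoters without a pooled peak gave 1.78 for GAGA, 0.823 for Zelda, 0.886 for the E-box, 1.08 for TATA, 0.334 for the initiator (adjusted exact p = 4.88e-69), 1.60 for Ets-like and 0.888 for E2F-like. The initiator value there reflects a high share at promoters without a pooled peak and cannot be read as depletion at summits. Windows 100 bp beside the summit gave 0.407 for the HINFP-like core (adjusted exact p = 0.0230), 1.32 for GAGA (0.000149), 1.05 for the E-box, 1.09 for CTCF-like, 0.985 for the initiator and 1.29 for E2F-like. Those given without a p did not pass. The strongest 50% gave 1.23 for Ets-like and 0.639 for E2F-like. With a replicate left out the range was 0.741 to 0.879 for GAGA, 0.880 to 1.09 for Ets-like and 0.692 to 0.719 for E2F-like.

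The difference in promoter share between strong and weak peaks was -2.35 points for the strongest and weakest 50%, -17.5 within 100 bp, 2.15 within 1000 bp, and -0.884 and 0.253 with a replicate left out.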

Other observations

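The comparison of the DRE and motif 1 between strong and weak peaks, the counts by number of TSSs, all tests of the 8-mers CACTGAGA and CCACTGTG and the test of GC content beside the summits were chosen only after the results they bear on were seen. The promoter elements that were most concentrated at summits were rarer within 50 bp of the summit in the strongest peaks. The DRE was within 50 bp of the summit in 14 of the 1583 strongest peaks (0.884%, interval 0.484 to 1.48) and in 64 of the 1583 weakest (4.04%, interval 3.13 to 5.13), with a Fisher's exact p of 5.75e-09 and the same adjusted value. Core promoter motif 1 was present in 5 of the strongest (0.316%) and 65 of the weakest (4.11%), with an adjusted p of 2.50e-14. Position as a part of this was not tested. In the strongest 1000 peaks the DRE had 7 matches within 50 bp of the summit and 22 at 100 to 150 bp, and motif 1 had 4 and 19. At 100 to 150 bp these were 2.2 and 1.9 matches per 100 peaks, and all IDR peaks had 2.41 and 1.83. The mean GC content was also lower at strong peaks, at 29.7% ± 9.03 (SD) in the strongest 1583 and 37.6% ± 10.6 in the weakest.

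The bound share of genes is given by their number of TSSs. Of 10246 protein-coding genes with 1 TSS, 2707 (26.4%) had an IDR summit within 250 bp, of 2566 with 2 TSSs 1112 (43.3%), and of 92 with 6 or more 52 (56.5%), values without a test. A gene with more TSSs also offers more sequence to be counted. Far from genes, 447 IDR summits (5.65%) lay over 10 kb from any TSS. Of the 19 summits in annotated transposons, 10 were in INE-1, which had 2235 insertions, and 3 in roo, which had 144.

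The empty histone cluster has a candidate technical explanation in repeated sequence. The median share of 32-mers within 250 bp of its TSSs that occur once in the genome sequence was 0%, against 100% in the other 25 lists, so reads from these promoters may have no single place. Against this stands 1 of the 4 pooled peaks, at 21425125, where 0% of the 32-mers were unique and a peak was called nonetheless, while the other 3 had 5.11% to 12.3%. The cuticle and receptor genes also had no bound member with a median of 100%, so a list can be empty without repeats. Those are other genes, so they do not test repeats as the cause at the cluster. Whether the protein binds the cluster stays open, and no biological explanation was tested.

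Summits of the strongest 1000 peaks were rich in A and T, with a mean GC content of 28.9% ± 8.78 (SD). This was 29.4% in the strongest 1000 of replicate 2 and 28.7% in those of replicate 4. A composition bias over fragments long enough to reach 200 to 400 bp from the summit would lower GC content there too. It was instead 44.8%, 2.49 points (SE 0.223) above random places. Random places do not give the local level around these peaks, so this comparison cannot decide that case. At 500 bp before and after the summit the mean GC content was 44.03% and 43.96%. The GC content at 200 to 400 bp was therefore not below that further out, which was not tested. At 100 bp before and after the summit the mean GC content was already 39.8% and 41.1%. A bias over shorter fragments could end there, so it stays open. Among the strongest 1000, the 450 promoter summits had 28.5%. Promoters without a pooled peak, at the same distances to a TSS, had 40.5%, a difference of -11.96 points (SE 0.472). The low GC content was therefore not that of promoters without a peak. Those promoters were picked for lacking a peak, so the composition of promoters in general was not excluded. A sequence preference is a hypothesis only, and no biological explanation was tested.

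The 8-mers CACTGAGA and CCACTGTG were more frequent beside summits than at them. They were in 307 and 319 of 15830 windows centred 100 bp away, against 35 and 58 of the flanks. Within 50 bp of IDR summits they had 70 and 76 matches, against 217 and 176 at 50 to 100 bp. At 450 to 500 bp they had 15 and 23. CACTGAGA was also among the 8-mers that held at summits on the test arms, with a ratio of 3.28 (adjusted exact p = 3.40e-06). Base composition was argued against in peaks outside the IDR list, which had no part in choosing the 8-mers. There the lower ranked of the pair was still within the top 0.655% of 8-mers of its composition. The ratios to the flanks in those peaks were 3.36 for CACTGAGA and 1.82 for CCACTGTG, below the 8.77 and 5.50 of the IDR peaks. Neighbouring peaks can share sequence: 333 pooled peaks and 169 IDR peaks had the same interval as another peak of their list. The windows of those outside the IDR list may therefore not be wholly separate from the windows on which the 8-mers were chosen. Copies of a repeat as the whole cause were argued against by windows with no masked base, where the mean ratio to the flanks was 5.37, but CACTGAGA fell there from 8.77 to 4.42, with 54 of its windows left, and CCACTGTG went from 5.50 to 6.32, so repeats stay open as part of the first. The lower mean ratio of the replicates, 6.89, decides nothing about 1 replicate alone, since 83.4% of the IDR peaks on which the 8-mers were chosen are among the strongest 7915 of both. No biological explanation was tested.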
